A study of Mus musculus with 8 samples.

How the data were processed

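FLAG-Ago HITS-CLIP, in which RNA crosslinked to a tagged Argonaute protein is immunoprecipitated and sequenced, was carried out on mouse forebrain. Per the labels, 5 libraries came from mice in which Cre under the Camk2a promoter switched on Flag-tagged Ago2, and 3 control libraries came from mice with the same Flag-Ago2 allele and no Cre. The libraries belong to 3 experiments. The control libraries are numbered 1, 2 and 3, and the Flag-Ago2 libraries 1, 2a, 2b, 3a and 3b. Per the labels' protocols, mice were 8 to 14 weeks old, tissue was irradiated 3 times with 400 mJ/cm2, RNase A was applied before and after immunoprecipitation with the M2 FLAG antibody, and libraries were made with Illumina's small RNA kit and 15 PCR cycles.

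Per the submitters' processing notes, reads were aligned with BWA to the mouse genome build mm10. The version of BWA, the way clusters were called, the libraries that entered them, any use of the controls and any removal of PCR duplicates are not given in the sources used here. The deposited table holds 70142 clusters of reads with position, strand and, per the file headers, a read count for each cluster, the genes overlapped in 3' UTR, CDS, 5' UTR, intron and antisense, circRNA identifiers, and 1281 miRNA columns. The deposited count is a whole number of reads per cluster, with a lowest value of 10, and no normalization is named. Per the file headers there is 1 value per cluster for the whole study, so the table has 0 columns that belong to a single library or group. The 8 libraries therefore have no depth of their own here, and no replicate spread can be given for any value.

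The design fixed before the data were examined compared Flag-Ago2 with control libraries by edgeR. It could not be run, because the table separates neither libraries nor groups. The fallback written with it was a description of the table's own values with no test, with named items ranked by reads. That description is given, and the tests below were added to it after the table was seen. No value below is a difference between Flag-Ago2 and control mice, and the background in control mice could not be set beside any value.

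The gene, cell type and miRNA lists and the rule for naming items were also fixed before the data were examined. The rule names Ago2 and Camk2a, the 10 genes with the most exonic reads, the 5 deepest clusters, the 2 members of each list with the most reads, the 5 seeds with the smallest p in each direction and every family of the fixed lists past the threshold. In 2 of the lists, only 1 of these members is named. Other genes and sites that are named were chosen after their values were seen, which is said where they appear.

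Each cluster was given 1 region in the order 3' UTR, CDS, 5' UTR, intron, antisense only and unannotated, from the table's own gene columns. Shares carry 95% Wilson intervals. Reads were amplified by PCR without molecular identifiers, so the intervals cover counting error only. Exonic reads of a gene are the reads of its 3' UTR, CDS and 5' UTR clusters, and 140 of the 23138 exonic clusters name more than 1 gene and count for each. Coordinates are 1-based on mm10, and GENCODE M21 on the same assembly gave exon lengths, UTR and CDS sequences and small RNA genes. A gene list was described by its mean log2(exonic reads + 1), set as a percentile among 10000 random lists of protein-coding genes matched on exon length, each member being drawn from the 200 genes nearest in length. Genes not expressed in brain are among those drawn. For 3 pairs of lists, a two-sided permutation test with 100000 permutations was made, with Benjamini-Hochberg adjustment over the 3 pairs. Both list tests were chosen after the table was seen.

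The seed definition behind the miRNA columns was worked out from the values. Counting the 6 bases complementary to miRNA bases 2 to 7, with an overlap of at least 1 base with the cluster, gave the same number in all of 16556 exonic clusters for 1281 of 1281 columns. The columns hold 885 distinct 6-mers, so miRNAs that share a 6-mer cannot be separated. The lists hold 30 families known to be abundant in brain and 20 of other tissues, of which miR-144 was left out because it shares its 6-mer with miR-101. Seed matches were compared with random placement by a relocation test, also chosen after the table was seen. Each cluster inside a single 3' UTR exon segment, 7137 clusters in 3823 genes, was moved to every possible position of the same 3' UTR, and the exact distribution of the summed count gave a two-sided p, adjusted by Benjamini-Hochberg over 885 seeds with a threshold of 0.05. The ratio of observed to mean relocated matches carries a 95% interval from 2000 bootstrap draws over genes. The same was done in CDS with 3871 clusters in 2541 genes.

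The relocation test was tested on simulated data. With clusters placed at random, it called 0 of 885 seeds, and 3.5% had an unadjusted p under 0.05. That placement is the null of the test itself. It holds no bias by bases, such as the rise with purines given below, so behaviour under such a bias was not simulated. With 20 seeds planted at a weight of 1.3 per match it called 15, with a median ratio of 1.27, and at a weight of 1.6 it called 19, with a median ratio of 1.56. Planting spilled over to neighbouring sequence: 21 of 541 seeds with nothing planted that share no 4-base end with a planted seed were also called. Of 200 random gene lists, 3.5% fell outside the middle 95% of percentiles.

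Alternatives tried were the share of reads, every region a cluster overlaps, clusters above the median number of reads, 3' UTR clusters alone, the highest cluster of a gene, clusters that name 1 gene, the central 50 bases of clusters, the same in 4 classes of reads, the deepest cluster of each gene, clusters that match 1 fixed family, removal of clusters with 8 bases of the complement of the 5' adapter, an excess over 6-mers of the same bases and an adjusted p under 0.01. The sequences of the kit's adapters were written from general knowledge, as the labels name the adapters without sequence. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used. Raw reads were not analysed here.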

Results

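The data describe where Argonaute-bound RNA fragments lay in the transcriptome of mouse forebrain, in a study that asked which miRNA seeds are targeted in Camk2a neurons. The study has 5 Flag-Ago2 libraries and 3 control libraries, and its deposited values are a single table of 70142 clusters, which together hold 1834586 reads; the libraries that entered it are not given. A cluster held between 10 and 17721 reads, with a median of 18, and its median width was 128 bases. Depth was concentrated in few sites: the 10 deepest clusters held 4.01% of the reads and the 1000 deepest 15.6%. A circRNA identifier was attached to 9059 clusters, or 12.9%. The reads of a cluster are pooled over libraries that the table does not name, so all values below lack a replicate check and a control value.

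Introns carried the largest group of clusters. They held 32704 clusters, or 46.6% (95% Wilson interval 46.3 to 47.0), and 41.4% of the reads. Coding sequence held 12960 clusters, or 18.5% (18.2 to 18.8), with 22.3% of the reads, and 3' UTRs held 9284, or 13.2% (13.0 to 13.5), with 16.2% of the reads. Clusters in 3' UTR and in CDS had a median of 21 reads each, against 18 in introns and 15 in the 12108 clusters with no annotation. The 5' UTRs held 894 clusters, or 1.27%. Regions were assigned by priority: when every overlap was counted, introns were touched by 61.5% of the clusters and CDS by 20.6%. The genes with the most intron-only clusters, named after their values were seen, were Rbfox1, a neuronal splicing regulator, with 335, Celf2 with 252, Nrxn3 with 241 and Ptprd with 221. Neither these counts nor the shares of the regions were set against the length of introns or other regions, so they do not show a preference.

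**Figure D1:**
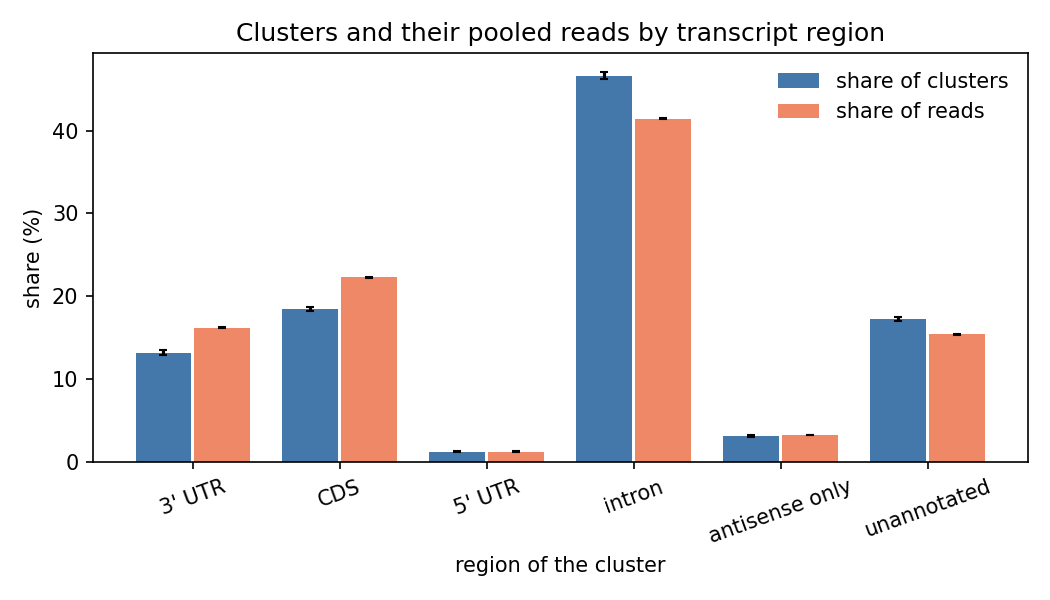
Share of clusters and share of pooled reads, in percent, by transcript region; bars are shares and error bars 95% Wilson intervals. Introns held 46.6% of clusters and 41.4% of reads, and 3' UTRs 13.2% and 16.2%.

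The deepest cluster lay on the plus strand of chromosome 17 at 24594948 to 24595106, in the coding sequence of Pkd1, which encodes polycystin 1. It held 17721 reads, and the same interval overlaps the annotated miRNA gene Gm24589. The second, on the plus strand of chromosome X at 61183216 to 61186181, held 12432 reads over 2966 bases. It lies opposite Cdr1, within the annotated lincRNA C230004F18Rik, and carries 12 circRNA identifiers. That cluster contained 139 matches to the miR-7 seed, or 46.9 per kb, against 0.430 per kb in all other clusters. No other cluster had more than 20 miR-7 matches. The remaining 3 of the 5 deepest clusters had no annotation: 5935 reads on the minus strand of chromosome 11 at 121105597 to 121105753, 5882 reads on the plus strand of chromosome 2 at 63750467 to 63750618, and 5786 reads on the plus strand of chromosome 1 at 97026235 to 97026485. Each of these 3 contained 1 match to the miR-128 seed. Annotated small RNA genes overlapped 194 clusters with 29449 reads, of which 40 clusters with 20951 reads overlapped miRNA genes. The cluster over Gm24589 alone held 17721 of these 20951 reads.

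Exonic clusters were found in 8110 genes, and 4863 genes had one in the 3' UTR. Pkd1 ranked highest with 17873 exonic reads, nearly all from the cluster above. Hnrnpf, which encodes an RNA-binding protein, followed with 5799 reads, 5730 of them in 1 3' UTR cluster. Acadvl, an enzyme of fatty acid oxidation, had 5742 exonic reads and Rps6kl1 had 3608, all in coding sequence. Smarcc2, a subunit of a chromatin remodelling complex, had 3412. The ubiquitin ligase gene Fbxo32 had 3232 reads, of which 3095 were in the 3' UTR. Strbp had 2983 exonic reads, Syt4, a synaptotagmin, 2677, Sft2d2 1678 and the histone methyltransferase gene Setd2 1511. A single cluster gave most reads of each of these genes, so their rank rests on 1 site each.

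Ago2 itself carried 5 exonic clusters with 139 reads, 2 of them in the 3' UTR. Camk2a, whose promoter drove Cre, carried 11 exonic clusters with 618 reads, 5 of them in the 3' UTR. The genes with the most 3' UTR clusters, named after their values were seen, were Tnrc6b with 22, the sodium-calcium exchanger Slc8a1 with 20, Adcy1 with 17 and the glial glutamate transporter Slc1a2 with 16. These counts were not set against 3' UTR length. Tnrc6b and Tnrc6a, which encode partners of Argonaute in silencing, led the miRNA machinery list with 1358 and 1213 exonic reads. In that list 11 of 13 members had an exonic cluster, and the list lay at percentile 99.3 among length-matched random lists.

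Markers of excitatory forebrain neurons were widely covered, with an exonic cluster in 11 of 12 genes, led by Camk2a with 618 reads and Bcl11b with 262. Striatal projection neuron markers had clusters in 10 of 12, led by Pde10a with 382 and Pde1b with 326. Interneuron markers had clusters in 6 of 12, led by the GABA-synthesising enzymes Gad2 with 146 and Gad1 with 117. Astrocyte markers had clusters in 12 of 12, led by Slc1a2 with 1105 and Aldoc with 209. Oligodendrocyte markers had them in 11 of 14, led by Mbp with 298 and Mag with 145. Microglial markers had them in 5 of 12, among them Cx3cr1 with 33, and endothelial and mural markers in 8 of 12, led by Flt1 with 169 and Pdgfrb with 76. The haemoglobin genes Hba-a1 and Hba-a2, near-identical copies that share their reads, had 303 each, and the other 3 red blood cell markers had no exonic cluster.

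Among length-matched random lists, the mean of the excitatory and the astrocyte list lay at percentile 100, above all 10000 draws. The striatal list lay at 99.98, the oligodendrocyte and red blood cell lists both at 99.9, the interneuron list at 93.04, the endothelial and mural list at 92.4 and the microglial list at 72.4. Mean log2(exonic reads + 1) over the 12 astrocyte markers was 6.84 ± 1.54 (SD across genes), against 5.72 ± 2.48 for the 12 excitatory markers. The difference of 1.13 did not pass a two-sided permutation test (p = 0.1996). Astrocyte markers exceeded the 12 microglial markers by 4.99 (permutation p = 2e-05, adjusted p = 6e-05). Excitatory markers exceeded the 12 interneuron markers by 2.65 (permutation p = 0.0357), which failed the correction over 3 pairs with an adjusted p of 0.0536. These tests do not match the lists on length: the means of length-matched random lists were 3.01 for astrocyte, 1.45 for microglial, 2.85 for excitatory and 2.00 for interneuron markers, so the differences are not free of length. Genes of a list are not independent replicates, and the random lists include genes not expressed in brain.

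The other gene lists were also widely covered, apart from the mitochondrial one. Voltage-gated ion channel genes had an exonic cluster in 20 of 20, among them the calcium channel Cacna1e with 593 reads. Glutamate synapse genes had one in 19 of 20, led by Gria3 with 489 and Dlg2 with 466. ERK pathway genes had one in 19 of 20, led by Pea15a with 403 and Rps6ka3 with 240. Activity-induced genes had one in 12 of 14, led by Homer1 with 171 and Egr1 with 125, and abundant housekeeping genes in 13 of 15, led by Actb with 286 and Eef2 with 274. These 5 lists lay at percentile 100. Genes on the fixed list of reported miRNA targets had one in 15 of 20, led by the splicing regulator Ptbp2 with 891 and Arhgap32 with 363, at percentile 98.1. The mitochondrial list had 0 of 11, because the table attaches no gene name to clusters on that chromosome.

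**Figure D2:**
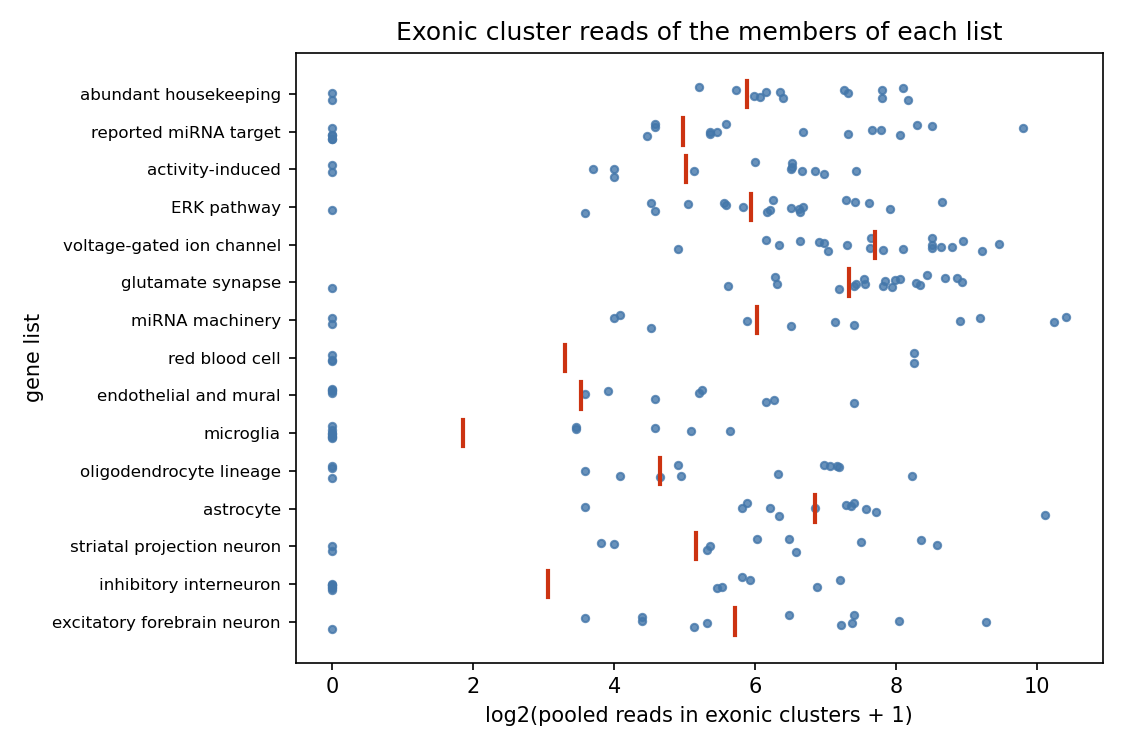
Pooled reads in exonic clusters of each gene, as log2(reads + 1), by gene list; points are genes and red bars list means. The mean was 6.84 for astrocyte, 5.72 for excitatory and 1.85 for microglial markers.

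Seed matches in 3' UTR clusters were set against random placement in the same 3' UTRs. The miR-128 seed match, a 6-mer also counted for miR-6539, had the smallest p of all 885 seeds, with 1043 matches against 657 by chance. Its ratio was 1.59 (95% bootstrap interval 1.51 to 1.67), with an adjusted p of 1.7e-46 in the relocation test. Next by p were miR-455-3p with a ratio of 1.64, miR-27 with 1.45, miR-29 with 1.56 and miR-139-5p with 1.53. The 6-mers of miR-455-3p and miR-139-5p both lie within the complement of the 5' adapter used to make the libraries. At the other end were miR-186-5p with 0.737, miR-340-5p with 0.706, miR-410-3p with 0.669, miR-694 with 0.747 and miR-466l-3p with 0.728, all of them seeds rich in A and U; against 6-mers of the same bases, miR-186-5p and miR-466l-3p were both at 1.01. In all, 378 of 885 seeds passed the threshold, 183 of them more frequent and the others less frequent than under random placement. In clusters that match 1 fixed family only, the miR-128 ratio was 1.16 and did not pass. That setting leaves out every cluster that also matches another fixed family, such as miR-27, whose 6-mer overlaps that of miR-128.

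Of the 30 brain-abundant families, 16 were more frequent in 3' UTR clusters and 3 less frequent, or 18 and 3 when adjusted over the list alone. Besides miR-128, miR-29 and miR-27, the higher families were miR-99/100 at 1.54, miR-181 at 1.32, miR-26 at 1.26, miR-137 at 1.20, the family of miR-132 and miR-212 at 1.19, that of miR-221 and miR-222 at 1.17, miR-101 at 1.16 and miR-124 at 1.15. The remaining higher families, those of miR-125, of miR-22, of miR-15, miR-16 and miR-195, of miR-23, and of miR-103 and miR-107, had ratios from 1.097 to 1.12. In clusters that match 1 fixed family only, 9 of the higher families, miR-124, miR-26 and miR-27 among them, had a ratio under 1. Leaving out clusters with another fixed family can lower the ratio of a seed that is more frequent, because other families were more frequent too. A ratio under 1 in that setting therefore does not show a lower frequency of the seed. The lower families were miR-17/20/93 at 0.882, miR-129 at 0.872 and miR-7 at 0.869. Against 6-mers of the same bases, 3 of these directions turned, with miR-125 at 0.931 and miR-17/20/93 and miR-7 both at 1.05. The let-7/98 family, at 1.13, missed the threshold over all seeds with an adjusted p of 0.0626 in the relocation test and passed it over the list alone with 0.0410; its log2 excess over 6-mers of the same bases was 0.38. The miR-9 family was at 0.999. The 6-mer of miR-101 overlaps those of miR-128, miR-27 and miR-132 when shifted by 1 or 2 bases, and that of miR-128 overlaps that of miR-27, so their ratios are not independent.

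Of the 19 families of other tissues, 4 were higher, namely miR-205 at 1.33, miR-375 at 1.31, miR-145 at 1.296 and miR-133 at 1.18. The same number were lower, namely miR-122 at 0.883, miR-143 at 0.864, miR-142 at 0.824 and the family of miR-200b and miR-429 at 0.767. Against 6-mers of the same bases miR-122 turned to 1.05. The median log2 ratio was 0.15 for brain-abundant families and -0.06 for those of other tissues. The difference of 0.21 had a two-sided permutation p of 0.0120, in a test that treats families with overlapping 6-mers as independent. It was no longer past the threshold under 7 of 10 alternatives, among them the comparison with 6-mers of the same bases, where it was 0.08 (permutation p = 0.0858), and clusters that match 1 fixed family, where it was 0.03 (permutation p = 0.805). Under the other 5 of these it was 0.18 to 0.38.

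**Figure D3:**
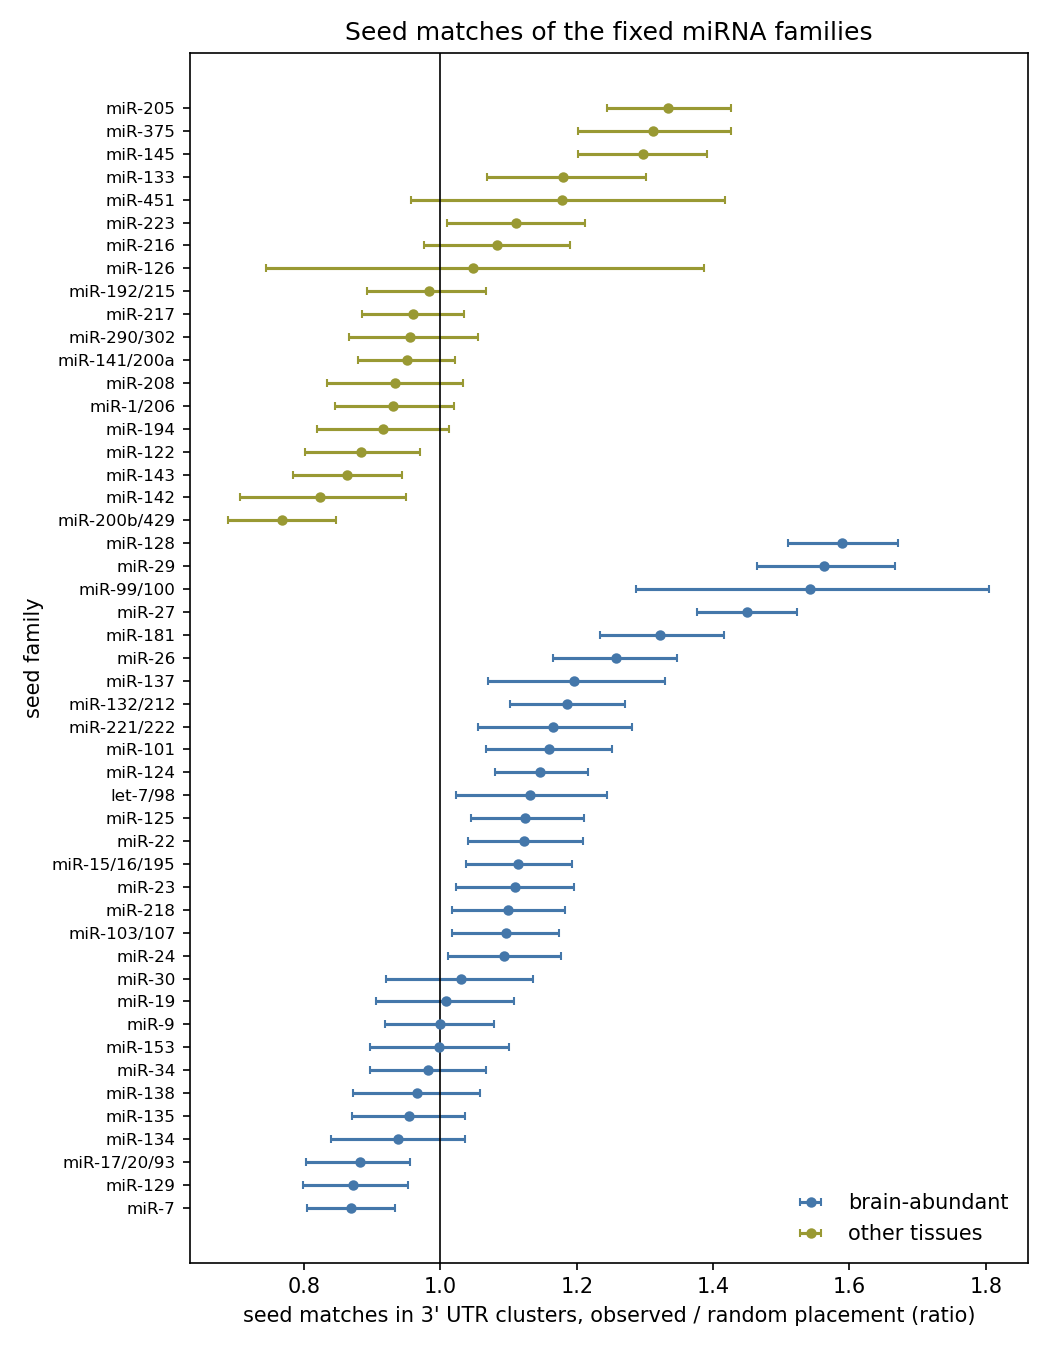
Ratio of seed matches in 3' UTR clusters to random placement, by miRNA family; points are ratios and bars 95% bootstrap intervals over genes. The ratio ranged from 0.767 for the family of miR-200b and miR-429 to 1.59 for miR-128.

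In coding sequence, 103 seeds were more frequent and 118 less frequent than under random placement. The test there covers only the 3871 clusters inside a single CDS exon segment, of 14443 that overlap CDS. The miR-128 seed again had the smallest p, with a ratio of 1.55 (1.42 to 1.68). It was followed by miR-3473c with 1.42, miR-670-3p with 1.42, miR-455-3p with 1.601 and miR-877-3p with 1.46. The lowest by p were miR-1940 with 0.711, miR-1964-5p with 0.718, miR-7 with 0.691, miR-3475 with 0.769 and miR-300-5p with 0.745. Among brain-abundant families, 7 were higher in CDS, namely miR-128, miR-29 at 1.33, miR-27 at 1.32, miR-181 at 1.22, miR-24 at 1.21, miR-9 at 1.20 and miR-125 at 1.19, and 1, miR-7, was lower. Of the other tissues, miR-145 at 1.32, miR-375 at 1.22 and miR-205 at 1.14 were higher, and miR-143 at 0.843, miR-217 at 0.805, miR-122 at 0.762 and miR-194 at 0.725 were lower. Against 6-mers of the same bases miR-205 turned there, to a log2 ratio of -0.03. The difference between the list medians, 0.19 on the log2 scale, did not pass the permutation test (p = 0.122).

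Matches of the leading families lay near the centres of 3' UTR clusters. Over 5798 clusters with room on both sides, miR-128 matches reached 2.49 times the mean of the same 3' UTRs in the 25 bases upstream of the centre. Those of miR-29 reached 2.502 times in the 25 bases downstream, and those of miR-181 1.77 times upstream. In these same bins miR-124 was at 0.988 and 1.29, and let-7/98 at 0.963 and 1.16. Against 6-mers of the same bases, however, the log2 excess in the central 50 bases was 1.09 for miR-128 and 0.82 for let-7/98. It was 0.74 for miR-29, 0.60 for miR-181 and 0.55 for miR-124, but -0.16 for miR-9. Families of other tissues, named here after their values were seen, also varied. Their excess was 0.57 for miR-223, 0.44 for miR-133 and 0.42 for miR-145, but -0.40 for the family of miR-200b and miR-429. The difference between the list medians of the log2 ratio in the central 50 bases, 0.37, did not pass (permutation p = 0.113). Central matches therefore did not set the brain-abundant list apart. The 6-mer GACTGT, which no miRNA column counts, reached 2.61 times the mean of the same 3' UTRs in the 25 bases downstream. It shares the bases ACTGT with the miR-128 6-mer and lies within the complement of the 5' adapter. The deepest 3' UTR clusters with a miR-128 match, named after their values were seen, were in Hnrnpf with 5730 reads, Fbxo32 with 3041 and Syt4 with 2619. Those with a miR-29 match were in Hnrnpf, Strbp with 2581 and Hmgcs1 with 534, and those with a miR-124 match in Sft2d2 with 1620, Tnrc6b with 581 and Tanc2 with 436.

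**Figure D4:**
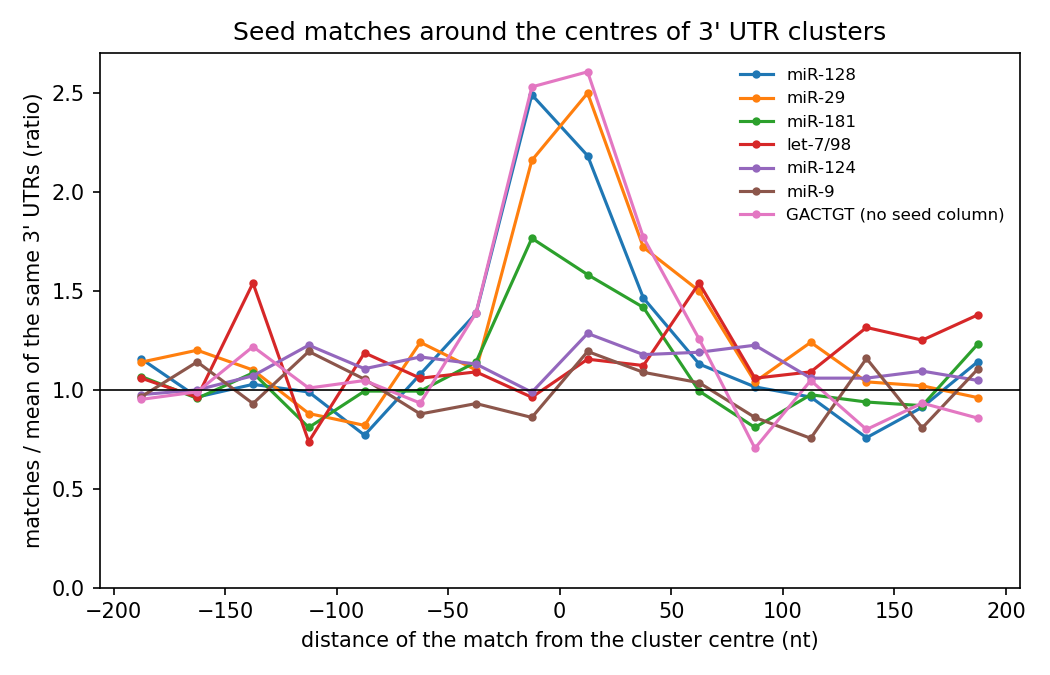
Seed matches per bin of 25 bases around the centres of 5798 clusters in 3' UTRs, divided by the mean of the same 3' UTRs; each line is a seed or 6-mer, by distance in nt. The miR-128 line peaked at 2.49, miR-29 at 2.502 and GACTGT at 2.61.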

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

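Of the tests in this part, 5 were written down before their result was seen, those on miR-128 matches preceded by C, on 8-base words of the adapter's complement, on its 6-mers apart from seeds, on the bases at cluster ends and on seed matches in astrocyte markers, and the others were chosen after.

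Signal lay in parts of the table that the comparisons of genes and seeds do not use. The table names a gene only on the opposite strand for 2192 clusters, or 3.13%. The deepest were the one opposite Cdr1 with 12432 reads and one opposite Invs with 5624, and the most numerous lay opposite Copg2, with 16 clusters, and Ube3a, with 10. Another 12108 clusters had no annotation. The mitochondrial chromosome carried 45 clusters with 6466 reads, of which 4092 came from the interval 3442 to 4085 that spans mt-Nd1, mt-Ti, mt-Tm and mt-Nd2. The controls cannot be separated, so none of these was compared with a background, and no explanation was tested for them.

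The first pattern weighed is the excess of 6-mers complementary to the 5' adapter: the 21 such 6-mers exceeded others of the same bases in 3' UTR clusters by a median of 0.40 on the log2 scale, 16 of them with a z above 3, against -0.02 for the adapter's own strand. The z makes no allowance for bases. Of the 19 6-mers complementary to the 3' adapter, 7 also had a z above 3, at a median excess of -0.001. Seeds that share the 6-mers complementary to the 5' adapter are not the whole cause of their excess over the same bases. The 14 in no miRNA column were counted only where they share no base with a seed called higher. They still exceeded others of the same bases counted that way by 0.22 (0.14 to 0.30). Away from all seed columns the excess was 0.32 (0.12 to 0.50). Their own ratio to random placement was 1.04 and 1.20, in that order, so part of the excess came from lower ratios of the others. Pairing of RNA fragments with the adapter during library preparation may add to the reads, but its test cannot be decided: on the log2 scale, 8-base words of the complement exceeded words with both outer bases changed by 0.22 (-0.05 to 0.45) in CDS, where the test was set, and by 0.45 (0.32 to 0.59) in 3' UTRs. As the whole cause of the miR-128 excess, adapter pairing is argued against only by the word set beforehand, CACTGTG. The first base of CACTGTG pairs with miR-128 and departs from the adapter's complement. That word kept a ratio of 1.604 (1.47 to 1.75), against 1.16 (1.01 to 1.34) for CACTGTA, which holds more adapter bases. After other bases, ACTGTG and ACTGTA did not clearly differ: 1.93 and 1.96 after G, 1.47 and 1.39 after A, 1.31 and 1.36 after T. No other biological explanation was tested, because the groups cannot be compared.

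The next pattern is the rise of the ratio with purines, from a median of 0.824 for 6-mers with 0 purines to 1.34 for those with 6 in 3' UTRs, and from 0.810 to 1.26 in CDS. RNase A, which cuts after C and U and was used before and after immunoprecipitation, is a candidate explanation whose test cannot be decided: the percentage of C or U at cluster ends differed from that 10 bases inside by -0.842 (-2.502 to 0.686) to 1.35 (-0.828 to 3.52) points, and cluster ends need not be fragment ends. G and C content alone is argued against, because at 3 G and C, 6-mers whose G and C are all G exceeded those with all C by 0.48 in 3' UTRs. With G only, the median ratio there rose from 0.883 at 1 G to 1.31 at 4. With C only, it stayed between 0.798 and 0.875. G is itself a purine, so these values do not separate a rise with purines from a rise with G. A preference of Argonaute or of its miRNAs for such sites stays open as untested.

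The last pattern is that all 12 astrocyte markers, which forebrain tissue expresses, carried clusters, although Flag-Ago2 was switched on in Camk2a neurons. It was not particular to astrocytes. Oligodendrocyte markers had clusters in 11 of 14 (percentile 99.9), and Hba-a1 and Hba-a2 had 303 reads each. Endothelial and mural markers had clusters in 8 of 12 (percentile 92.4) and microglial markers in 5 of 12 (percentile 72.4). Transcript length alone is argued against for the astrocyte list, which lay at percentile 100 among length-matched lists. Those lists include genes not expressed in brain, and the excitatory and housekeeping lists also lay at 100. The percentile therefore does not bear on why astrocyte markers were covered as widely as excitatory ones. RNA of abundant transcripts carried along as background, or reads from control libraries, if the pool holds them, could give such clusters. The test cannot be decided: seed matches of the called brain-abundant families in cluster centres had a ratio of 1.16 (0.49 to 1.91; 36 clusters) in astrocyte markers and 1.17 (0.35 to 2.01; 18 clusters) in excitatory markers, too few to separate. Slc1a2, the deepest, had 1105 reads, against 618 for Camk2a, and expression of Flag-Ago2 outside Camk2a neurons stays open as untested.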

How the results depend on the processing

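The alternatives by central bases, by class of reads within them, by deepest cluster of each gene, by removal of adapter complement, by 6-mers of the same bases, by every overlap and by clusters naming 1 gene were chosen after the results were seen; the others were planned. No paired analysis was possible because the table holds no values per library. For the same reason the planned changes of scaling, tool, count filter, pseudocount, replicate block, summed libraries, set test and left-out libraries were not run. Matches of 8 bases were not run because match types are not given, and counting each position once changes nothing, as all 70142 positions are distinct.

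Of the alternatives to the main results, 85 kept direction and side of the threshold or stayed within 1.5 times a count, 42 moved and 9 fell short of the threshold. Of those to single genes, families and seeds, 200 stayed the same, 29 moved, 109 fell short of the threshold and 19 reversed. The cause was not tested except where named.

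The plan had the share of reads as the main value for regions and the share of clusters as its alternative, and they are reported the other way round. By share of reads, 3' UTRs took 16.2%, CDS 22.3%, introns 41.4% and unannotated clusters 15.4%. Among clusters with more than the median reads, 3' UTRs took 15.6%, CDS 21.4% and unannotated clusters 12.8%. With every overlap counted, CDS took 20.6% and introns 61.5%, by construction. With 3' UTR clusters alone, 4863 genes had a cluster, also by construction, and the excitatory markers exceeded interneuron markers by 1.76 (permutation p = 0.164). The list of reported targets fell to percentile 96.5 in clusters above the median reads. The percentiles of the other lists stayed on the same side of the bounds under every alternative run.

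Among 3' UTR clusters above the median reads (3548 clusters), 129 seeds were lower, 10 brain-abundant families higher and 1 of other tissues lower, and the brain minus other difference was 0.18 (permutation p = 0.0511). At an adjusted p under 0.01, 126 seeds were lower, 10 brain-abundant families higher and 1 lower, and 2 of other tissues lower. Within the central 50 bases, 5 brain-abundant families were lower and the difference was 0.37 (permutation p = 0.113). With the deepest cluster of each gene, 1 family of other tissues was lower, and without adapter complement, 2 were.

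Splitting the central bases by reads left fewer clusters in each class. At 10 to 14 reads, 91 seeds were higher and 72 lower, 4 brain-abundant families were higher and 1 lower, 2 families of other tissues were higher and 2 lower, and the difference was 0.20 (permutation p = 0.367). miR-124 reversed to 0.853, miR-23 to 0.947 and miR-142 to 1.05. At 15 to 24 reads, 118 seeds were higher and 86 lower, 5 brain-abundant families were higher, and the difference was 0.19 (permutation p = 0.259). At 25 to 49 reads, 117 seeds were higher and 123 lower, 9 brain-abundant families were higher, 2 of other tissues were lower, and the difference was 0.38 (permutation p = 0.176). At 50 reads or more, 42 seeds were higher and 9 lower, 5 brain-abundant families were higher and 0 lower, and 1 of other tissues was higher and 0 lower. There miR-122 reversed to 1.29, and the difference, 0.74 (permutation p = 0.00775), stayed past the threshold.

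Clusters that match 1 fixed family only (1320) left 1 brain-abundant family higher, 0 of other tissues higher and 0 lower, with a difference of 0.0329 (permutation p = 0.805). In them miR-124 reversed to 0.992, miR-26 to 0.760, miR-27 to 0.948, miR-23 to 0.723, miR-101 to 0.987, miR-137 to 0.980, the family of miR-15, miR-16 and miR-195 to 0.945, miR-22 to 0.943 and that of miR-221 and miR-222 to 0.749. Fewer clusters and the removal of sites shared with overlapping seeds enter by construction. So does the removal of every cluster with another fixed family, which can lower the ratio of a seed that is more frequent. These reversals therefore do not show that the seeds were less frequent. The miR-128 ratio there was 1.16, short of the threshold, and it stayed past the threshold, at 1.59 to 3.08, under the other alternatives that test it. Against 6-mers of the same bases the brain minus other difference was 0.0762 (permutation p = 0.0858). The ratios of miR-125 (0.931), miR-17/20/93 (1.05), miR-7 (1.05), miR-122 (1.05), miR-186-5p (1.01) and miR-466l-3p (1.01) reversed there, and that of miR-128 was 1.55.

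Depth limits these results through the pooled reads: with a lowest count of 10 and a median of 18, and no value per library, neither background nor spread between mice can be measured.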

Other observations

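The values in this part were chosen after the results were seen, and no explanation is offered for them.

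Clusters with a miR-128 match were deeper than others. Of the 33155 clusters with 10 to 17 reads, 9.35% (95% Wilson interval 9.04 to 9.67) held one, against 11.4% of the 32373 with 18 to 49 reads, 16.8% of the 3651 with 50 to 99 and 27.5% (24.8 to 30.4) of the 963 with at least 100. The density rose from 0.713 to 2.27 matches per kb, so the greater width of deep clusters, a median of 146 bases against 125, did not account for it. Other families rose as well between the lowest and the highest class: miR-27 from 8.55% to 21.4% (0.656 to 1.67 matches per kb), miR-29 from 6.06% to 12.2% (0.448 to 1.14), miR-124 from 5.09% to 13.3% (0.376 to 0.785), let-7/98 from 2.19% to 6.23% (0.157 to 0.344), miR-9 from 4.25% to 8.93% (0.312 to 0.527) and, least, miR-181 from 5.22% to 8.93% (0.383 to 0.50025). Of the 10 deepest clusters 5 held a miR-128 match, and of the 30 deepest 12.

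The miR-128 6-mer was also denser than the median of the other seed columns of the same bases in each class of region, by 1.63 on the log2 scale in 3' UTRs, 1.54 in CDS, 1.72 in introns, 1.92 in unannotated clusters, 1.67 in antisense-only clusters and 1.19 in 5' UTRs. That of miR-27 was denser by 1.585, 1.49, 1.57, 1.71, 1.36 and 1.304 in the same order, above miR-128 in 5' UTRs. That of miR-455-3p was denser by 0.88 to 1.27. In 3' UTRs the same measure was 0.95 for miR-139-5p, 0.81 for miR-181 and 0.74 for miR-124. It was 0.48 for miR-9, 0.01 for miR-29 and -0.08 for let-7/98. None of these densities was set against random placement. Against random placement, the miR-128 log2 excess over 6-mers of the same bases was smaller, 0.63 in 3' UTRs and 0.66 in CDS. Introns and the other classes were not tested that way.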
